A study of Mus musculus with 8 samples.

How the data were processed

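RNA from a piece of ileum of about 4 cm per mouse was measured on 8 Affymetrix arrays, 4 from voglibose mice and 4 from water mice, with 250 ng of total RNA per array. Groups and replicate numbers were taken from the sample labels, which describe 4 mice per group and no batch. The p-values of single genes and of the permutation tests measure the spread between these mice. Those of the list test with a preset correlation, described below, do not. Scan dates and slides are not given in the sources used here, so a batch could not be tested.

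The values are log2 signals per probe set as the authors deposited them, to 2 decimals. Per the submitters' processing notes, RMA (background correction, quantile normalization and summarization of probes into probe sets) and the Transcriptome Analysis Console were used, with no versions. The log2 scale is not stated and was read from the deposited values, which ran from 2.09 to 19.55 with nearly equal medians in all arrays. The exact settings of the normalization and the genome build are not given in the sources used here, so no coordinates are reported. Normalization across arrays brings the arrays towards a common distribution, so a change in the total amount of RNA would not be seen. The deposited distributions still differed slightly, with upper quartiles from 9.04 to 9.22. A probe set near the low end of the scale carries mainly background, and the log2 difference of a dim gene is then too small. Signals at the bright end can approach saturation, which also makes differences smaller.

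All 22206 probe sets entered the tests, with no filter. Of these, 19572 had 1 gene symbol in the platform annotation, 0 had several and 2634 had none and are unnamed here. All 19572 symbols were matched to current names through their gene identifiers in a mouse RefSeq table (GRCm38.p6), used for names alone. For the 55 genes with over 1 probe set, the probe set with the highest mean was used. No array held values from another array: at most 1.27% of probe sets were identical between 2 arrays.

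Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend or robust fitting), 2-sided, with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05. The moderated variance had 11.1 total degrees of freedom, of which 5.09 came from the prior. The count at a fold change over 1.2 and an unadjusted p under 0.05 follows the threshold in the submitters' design text, which names no test. Differences are voglibose minus water on the log2 scale, with the moderated SE and 95% intervals. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

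Before the data were examined, 53 gene lists were fixed: pathways and complexes of the gut, and markers of the cell types an ileal sample could hold, with neighbouring pancreas, liver, fat and blood. Of these, 52 had at least 5 measured members and were tested, and the erythrocyte list was not. Each list was tested with limma's camera with a preset correlation of 0.01, with camera with the correlation estimated in each list, with fry, and with an exact 2-sided permutation test of its mean per mouse over 70 arrangements, whose smallest p is 0.0286. P-values were adjusted over the 52 lists. Camera asks whether a list differs from the other genes, and fry whether its genes move on balance in 1 direction. At the preset correlation, the members of a list count as nearly independent. A small p from that test can therefore arise from genes that vary together between mice, whatever their group.

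The genes named were set by a rule fixed at the same time: a panel of 28 genes whatever their values, of which 26 are reported here, the 12 genes with the largest rise and the 12 with the largest fall past the threshold or, where fewer passed, those with the smallest p among genes whose higher group mean lay above the median of all probe sets, leaving out predicted models, and up to 4 members with the smallest p in each list described. The lists described are those past camera's preset test, those on the gut hormones, stress, inflammation, barrier, bile acids and region of the intestine, and fatty acid oxidation and cell death. The choice of lists beyond those that passed was made after seeing the data.

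The tests were tested on simulated data made from the means and spread of these arrays over 22206 probe sets, in 20 runs with 50 genes changed at each size. At an adjusted p of 0.05, 11.9% of genes changed 1.5-fold were recovered, 71.8% at 2-fold, 96.9% at 3-fold and 98.9% at 4-fold, with 5.35% false calls. The changed genes were drawn from probe sets above the median signal, and the noise was independent between genes. Recovery of dim genes, or under spread shared between genes as in these mice, was not simulated. For lists of correlated members without any group effect, camera's preset test called 12.6 of 52 lists on average (5 to 21), and the estimated correlation called 0.

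Alternatives planned before the data were examined were another normalization, filters on dim probe sets, the replicate number as a block, other variance models and array weights, the B cell or smooth muscle list as a covariate, other thresholds and set tests, and leaving out each mouse in turn. After seeing the data, a fit without water mouse 4 and voglibose mouse 2 and a fit with the distal ileum list as a covariate were added.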

Results

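Expression was measured with Affymetrix arrays in the ileum of male KKAy mice, a strain that carries the yellow agouti allele and becomes obese and diabetic. The mice ate a diet with 45% of its energy from fat, and after 4 weeks on it they received voglibose at 1 mg/kg or water by daily gavage for 8 weeks. Voglibose inhibits the alpha-glucosidases of the intestinal brush border and so slows the release of glucose from starch and sucrose. Each group held 4 mice with 1 array each, and the comparison of the groups asks which ileal transcripts differ after treatment. The 8 arrays gave log2 signals for 22206 probe sets, of which 19572 carried 1 gene symbol. Array medians lay between 5.89 and 5.94, and correlations between arrays ran from 0.982 to 0.994. The first principal component took 31.1% of the variance and the next 19.2%. The number of arrays limits the precision, and the median SE of a log2 difference between the groups was 0.18.

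Acot12, a thioesterase that hydrolyses acetyl-CoA, had the smallest p of the whole array, with 12.51 ± 0.22 in water mice and 10.96 ± 0.55 in voglibose mice (log2 signal, SD, n = 4), a difference of -1.55 ± 0.25 (SE). Among the genes with the smallest p, 3 belonged to monocytes and macrophages or their recruitment: the chemokine Ccl8 (-1.52 ± 0.33), the chemokine receptor Ccr2 (-0.97 ± 0.18) and the lipopolysaccharide co-receptor Cd14 (-0.89 ± 0.19). The other genes with lower signal in voglibose mice included Apool, a subunit of the mitochondrial cristae junction complex (-0.94 ± 0.17), Coq3, an enzyme of ubiquinone synthesis (-0.65 ± 0.14), and Pdcd10 (-0.80 ± 0.17). Eef1akmt1, Zfp820, Mapk8ip3, Vma21 and Pus3 completed the 12 of this direction, whose differences ran from -0.61 to -1.55. In the opposite direction stood Pstpip1, a cytoskeletal adaptor of blood cells (1.13 ± 0.23), Fbp1, the fructose bisphosphatase of gluconeogenesis (1.06 ± 0.23), and Kyat1, a kynurenine aminotransferase (0.77 ± 0.19). Decr2, a peroxisomal enzyme of fatty acid breakdown, differed by 0.52 ± 0.13, and F8a, Aasdh, Rab11fip3, Etl4, Anxa9, Ccdc13, Efna1 and Kat7 completed the 12 genes. In all 24 genes the 4 voglibose mice lay on 1 side of the 4 water mice.

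None of these 24 genes passed the test over all genes, and the adjusted p was 0.652 for each (limma, Benjamini-Hochberg). No probe set of the array did: 0 were called with limma and 0 with a linear model without moderation of the variance. At an unadjusted p under 0.05 there were 1671 probe sets, 7.52% of the array, and all of them also differed by more than 1.2-fold, with 684 higher and 987 lower in voglibose mice (59.1% lower). This share became nearly even after a further quantile normalization, so the excess of lower probe sets depends on the normalization. The groups did not overlap in 966 probe sets, 4.35% of all, where chance alone gives 2.86%. The count of 1671 fell to 969 when voglibose mouse 1 was left out, and it was 1144 without water mouse 4 and voglibose mouse 2, the mice with the lowest ileal markers, a choice made after seeing the data.

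Genes of carbohydrate digestion and sugar transport had higher signal in voglibose mice, with differences from 0.06 to 1.08 in 13 of 13 measured members. The fructose transporter Slc2a5 had the largest, at 13.71 ± 0.62 in water and 14.79 ± 0.68 in voglibose mice (SD, n = 4; 95% interval of the difference 0.29 to 1.87). The glucose cotransporters Slc5a1 and Slc5a4b differed by 0.42 ± 0.24 and 0.59 ± 0.38 (SE), and the basolateral glucose transporter Slc2a2 by 0.22 ± 0.27. Without water mouse 2 these differences were 0.16, 0.39 and -0.077, and without voglibose mouse 3 that of Slc5a4b was 0.92. The brush border enzymes that voglibose inhibits, sucrase-isomaltase (Sis) and maltase-glucoamylase (Mgam), were among the brightest transcripts, with 18.44 ± 0.15 and 18.24 ± 0.15 in water mice and differences of 0.08 ± 0.14 and 0.20 ± 0.14 (0.019 and 0.13 without water mouse 2). As a group the list rose by a mean of 0.49 (limma's camera with a preset correlation, adjusted p = 0.000934), and adjusted p = 0.875 with an estimated correlation. No member passed over all genes and 0 passed adjusted over the list alone. The lowest list mean was that of water mouse 2, at -1.21, which also had the highest signal of the distal ileal gene Fabp6, and without this mouse the mean difference was 0.17 and the list no longer passed (adjusted p = 0.216).

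Fructolysis and gluconeogenesis genes also rose as a list, by a mean of 0.30 over 9 measured members, 6 higher and 3 lower (camera adjusted p = 0.0499). The call was lost with adjusted p = 0.875 with an estimated correlation, and in 8 of 19 refits the preset test did not pass, with adjusted p up to 0.184. Fbp1 passed when adjusted over the list alone (adjusted p = 0.00563), and 0 members passed over all genes. The fructose-metabolizing enzymes Tkfc, Khk and Glyctk differed by 0.64 ± 0.22, 0.37 ± 0.23 and 0.31 ± 0.23 (SE), and without water mouse 2 those of Khk and Glyctk were 0.15 and 0.088 (Khk 0.56 without water mouse 4).

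**Figure D1:**
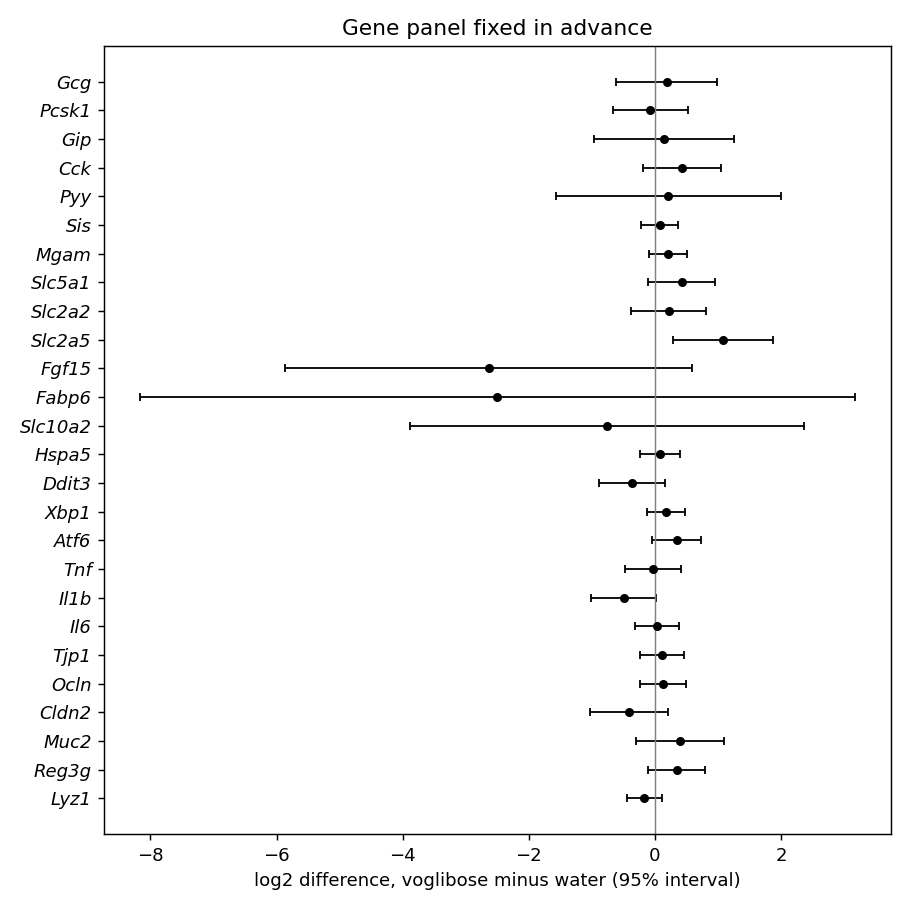
The plot shows the log2 difference between voglibose and water mice (x axis; points, with bars for the 95% interval from limma, 4 mice per group) for the 26 measured genes of the panel fixed in advance. The interval leaves out 0 for 1 gene, Slc2a5, and is widest for the ileal bile acid genes Fabp6, Fgf15 and Slc10a2.

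No gut hormone gene passed the test over all genes. Gcg, which encodes proglucagon and thereby GLP-1, had 11.88 ± 0.58 in water and 12.06 ± 0.73 in voglibose mice (SD, n = 4), a difference of 0.19 with a 95% interval from -0.61 to 0.99, and without voglibose mouse 4 it was -0.07. Pcsk1, the convertase that cuts proglucagon in enteroendocrine cells, differed by -0.07 ± 0.27 (SE), Gip by 0.14 ± 0.50, Pyy by 0.21 ± 0.81 and Cck by 0.43 ± 0.28 (0.21 without water mouse 2 and 0.67 without water mouse 4). Pyy was lowest in water mouse 4 and voglibose mouse 2 (8.44 and 8.50, others 10.97 to 12.16), and Gip was highest there (11.74 and 11.71). These mice also had the lowest means of the distal list, which holds Pyy, so the spread of both hormones ran with the regional genes. Tac1, Tph1 and Chga, further enteroendocrine markers, differed by -0.27 ± 0.18, -0.37 ± 0.26 and 0.22 ± 0.16. Tac1 was -0.14 without voglibose mouse 1, Tph1 -0.16 without water mouse 4 and -0.56 without water mouse 2, and Chga 0.14 without voglibose mouse 3. The enteroendocrine list held 10 higher and 12 lower members, with a mean difference of -0.03, and of 0.0014 after a further quantile normalization (camera adjusted p = 0.883). The list of nutrient receptors that trigger GLP-1 secretion had 10 higher and 7 lower members (mean -0.06, median 0.07, camera adjusted p = 0.831). Its mean was -0.029 without water mouse 1 and -0.096 without water mouse 4. The genes below are members of this list. In it Gnat3, the taste G protein gustducin, passed adjusted over the list alone (-0.77 ± 0.20; adjusted p = 0.0401) and not over all genes, at 4.60 in water and 3.84 in voglibose mice, near the lower quartile of the arrays (4.05 to 4.18). Trpm5, the cation channel of taste signalling, and the fatty acid receptor Ffar4 differed by -0.73 ± 0.25 and -0.46 ± 0.18.

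Genes of the unfolded protein response differed little. Hspa5, the main chaperone of the endoplasmic reticulum, differed by 0.08 ± 0.14 (0.16 without voglibose mouse 2 and 0.038 without water mouse 3), the sensor Atf6 by 0.35 ± 0.17 (0.21 without water mouse 4), the transcription factor Xbp1 by 0.18 ± 0.14 (0.11 without water mouse 2) and the stress-induced factor Ddit3 by -0.36 ± 0.24 (-0.59 without water mouse 2). Sdf2l1, Asns and the chaperone Calr differed by -0.29 ± 0.14, -0.47 ± 0.22 and 0.28 ± 0.13. The list of 30 measured members had a mean difference of 0.05 (0.0043 without water mouse 2), 19 higher and 11 lower, and no member had an unadjusted p under 0.05 (camera adjusted p = 0.230). Over the 26 panel genes the adjusted p from limma ran from 0.652 to 0.987.

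Inflammatory cytokine and chemokine genes moved in both directions, 18 higher and 23 lower of 41 measured (mean -0.05, camera adjusted p = 0.672). The mean was -0.022 without water mouse 4 and -0.082 without water mouse 2. Il1b had 7.58 ± 0.08 in water and 7.09 ± 0.54 in voglibose mice, a difference of -0.50 with a 95% interval from -1.01 to 0.02, and of -0.77 without voglibose mouse 3. Tnf and Il6 had 3.85 and 2.87 in water mice, below the lower quartile of the arrays, and differed by -0.03 ± 0.20 and 0.03 ± 0.16. The calprotectin genes S100a8 and S100a9 differed by -0.48 ± 0.17 and -0.58 ± 0.17, the acute phase gene Saa3 by -0.55 ± 0.18 and the chemokine gene Ccl4 by 0.57 ± 0.18. Group means of these genes all lay below the array medians (5.89 to 5.94), so their signals were dim. Among barrier genes, the goblet cell mucin Muc2 differed by 0.40 ± 0.32 (0.073 without water mouse 4 and 0.61 without voglibose mouse 2), the antimicrobial lectin Reg3g by 0.35 ± 0.20 (0.17 without water mouse 3) and lysozyme of Paneth cells (Lyz1) by -0.17 ± 0.13. The junction genes Cldn15 and Tjp3 differed by 0.61 ± 0.20 and 0.43 ± 0.17, Tjp1 and Ocln by 0.12 ± 0.16 and 0.13 ± 0.17, and Cldn2 and Cldn5 by -0.41 ± 0.28 (-0.11 without water mouse 2) and -0.25 ± 0.15 (-0.14 without water mouse 4). Tjp1 was 0.019 without water mouse 4 and Ocln 0.049 without voglibose mouse 3. Both rose without voglibose mouse 2, to 0.21 and 0.27. In the junction list 17 of 23 members were higher (mean 0.04, camera adjusted p = 0.294, and 0.875 with an estimated correlation). The list passed camera's preset test in 3 refits (adjusted p = 0.0328 to 0.0468). No member of these lists passed over all genes and 0 passed adjusted over the list alone.

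Interferon-stimulated genes had lower signal in voglibose mice, in 37 of 38 measured members, by a mean of -0.99. Ifit3, an antiviral effector, had 11.20 ± 1.70 in water and 9.12 ± 1.06 in voglibose mice (SD, n = 4; difference -2.08 ± 0.75, SE). Oasl1, the immunity GTPase Irgm1 and the guanylate-binding protein Gbp2 differed by -1.31 ± 0.46, -1.12 ± 0.40 and -0.61 ± 0.19. The list fell by camera's preset test (adjusted p = 9.33e-13), and adjusted p = 0.875 with an estimated correlation, which was 0.776 in this list. Per mouse the list mean was -0.53, 0.01, 0.87 and 1.64 in water and -0.73, 0.38, -0.13 and -1.50 in voglibose mice, so the groups overlapped (exact permutation p = 0.171). The difference was -0.61 without water mouse 4 and -0.66 without voglibose mouse 4. Unadjusted p was under 0.05 for 14 members, 0 passed over all genes and 0 adjusted over the list alone.

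Subunits of oxidative phosphorylation were lower in 63 of 75 members, by a mean of -0.27, and 27 had an unadjusted p under 0.05. Ndufb2, Ndufc2 and Ndufb4 of complex I differed by -0.81 ± 0.20, -0.70 ± 0.18 and -0.65 ± 0.17, and Atp5md of the ATP synthase by -0.64 ± 0.17. Proteasome subunits were lower in 31 of 38 members, by a mean of -0.29, with Psmc6 at -0.64 ± 0.15, Psma5 at -0.83 ± 0.20, Psma3 at -0.88 ± 0.26 and Psma1 at -0.75 ± 0.22. Psmc6 and Psma5 passed adjusted over the list alone (smallest adjusted p = 0.0360) and not over all genes, while 0 oxidative phosphorylation subunits passed adjusted over the list alone. Cytosolic ribosomal proteins were lower in 50 of 63 members, by a mean of -0.17, among them Rpl22l1 (-0.65 ± 0.22), Rps27l (-0.51 ± 0.21), Rpl38 (-0.41 ± 0.18) and Rpl36a (-0.44 ± 0.19). Over the whole array, 59.1% of the probe sets at an unadjusted p under 0.05 were lower too, an excess that depended on the normalization. It was larger among probe sets above the median signal, where the members named here lie. The counts of lower members are not corrected for it. The 3 lists fell by camera's preset test (adjusted p = 9.33e-13, 1.49e-07 and 0.000132), and each call was lost with adjusted p = 0.875 with an estimated correlation. The exact permutation p of the list mean was 0.0571 for oxidative phosphorylation, 0.0571 for the proteasome and 0.286 for ribosomal proteins. The ribosomal list no longer passed the preset test without water mouse 2 or without voglibose mouse 1 (adjusted p up to 0.141), where its mean difference was -0.099 and -0.093, and that of oxidative phosphorylation was -0.18 without water mouse 4.

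**Figure D2:**
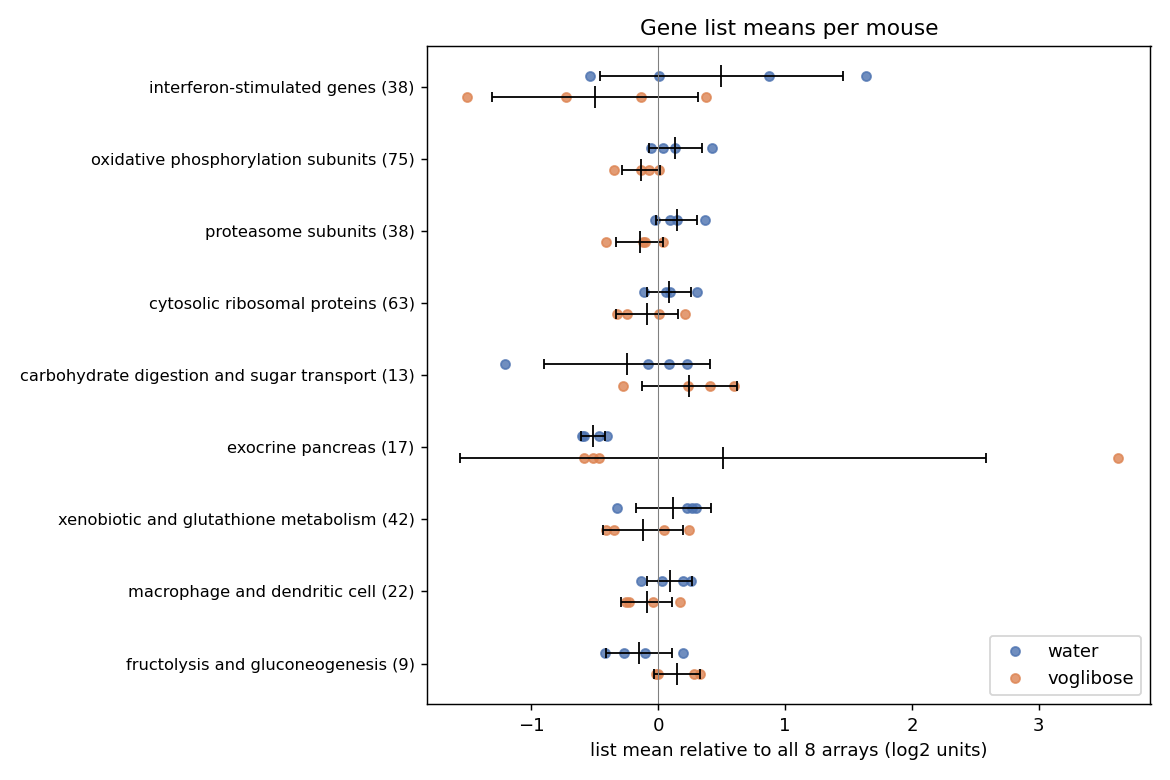
The plot shows the mean of each gene list in each mouse (x axis, log2 units relative to the mean of all 8 arrays; points are mice, bars the group mean and SD, number of measured genes in brackets) for the 9 lists past camera's preset test. The groups overlap in every list, and the exocrine pancreas list stands at 3.62 in voglibose mouse 2 and between -0.60 and -0.40 in the other 7 mice.

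Genes of xenobiotic and glutathione metabolism were lower in 30 of 42 members, by a mean of -0.24. The carboxylesterase Ces1f had 9.61 ± 0.44 in water and 7.83 ± 1.63 in voglibose mice (SD, n = 4), the glucuronosyltransferase Ugt2b5 differed by -0.93 ± 0.37 (SE), the glutathione transferase Gsta3 by -0.51 ± 0.14 and the sulfotransferase Sult1d1 by -0.49 ± 0.15. Macrophage and dendritic cell markers were lower in 15 of 22 members, by a mean of -0.18, with Ccr2 and Cd14 passing adjusted over the list alone (smallest adjusted p = 0.00601) and 0 over all genes. The mannose receptor Mrc1 and the lysozyme Lyz2 differed by -0.42 ± 0.17 and -0.29 ± 0.15. Both lists fell by camera's preset test (adjusted p = 0.0183 and 0.0499), and both calls were lost with adjusted p = 0.875 with an estimated correlation. The xenobiotic list no longer passed in 5 of 19 refits and the macrophage list in 9 of 19 (adjusted p up to 0.218 and 0.236). The xenobiotic difference ran from -0.14 without voglibose mouse 3 to -0.38 without water mouse 2.

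Fatty acid oxidation genes and targets of the lipid-sensing receptor PPAR alpha were lower in 24 of 35 members (mean -0.15, camera adjusted p = 0.111, and 0.875 with an estimated correlation). They passed camera's preset test in 2 refits (adjusted p = 0.0168 and 0.0277). Acot12 passed adjusted over this list alone (adjusted p = 0.00210) and not over all genes, Vnn1 and the mitochondrial isomerase Eci1 differed by -0.74 ± 0.27 and -0.45 ± 0.16, and the peroxisomal thiolase Acaa1a by 0.40 ± 0.16. In the cell death list 16 of 23 members were lower, by a mean of -0.37 and a median of -0.13, most of the mean coming from Gsdmc2 and Gsdmc4, and the list means of the 4 voglibose mice lay below those of the 4 water mice, at an exact permutation p of 0.0286, the smallest that this design allows. The gasdermins Gsdmc4 and Gsdmc2 of this list differed by -2.62 ± 1.10 and -2.78 ± 1.21 (-1.31 and -1.39 without water mouse 2), the death receptor Fas by -0.70 ± 0.22 and Casp1 by -0.38 ± 0.15. Adjusted over the 52 lists this p became 0.880, but 1 list at the smallest possible p cannot pass that adjustment. Of the 52 lists, 1 had an exact permutation p under 0.05, where simulated lists without a group effect gave 1.95 on average. Chance alone thus gives as many. Camera gave adjusted p = 0.111 with the preset correlation and 0.875 with an estimated correlation. The list passed camera's preset test in 3 refits (adjusted p = 0.00785 to 0.0328). C1galt1c1 of mucin glycosylation and the phosphofructokinase Pfkm of glycolysis, named after their values were seen, passed adjusted over their lists alone (adjusted p = 0.0469 and 0.0438).

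Bile acid genes of the ileum differed more between mice of 1 group than between the groups. Fabp6, the ileal bile acid binding protein, was 8.51, 17.50, 14.11 and 4.01 in the 4 water mice and 8.14, 3.54, 10.78 and 11.68 in the 4 voglibose mice, a difference of -2.50 ± 2.58 (SE). Fgf15, the ileal hormone that represses bile acid synthesis in the liver, differed by -2.64 ± 1.46 and reached 13.62 in water mouse 2, without which the differences of Fabp6 and Fgf15 were -0.34 and -0.86 (Fabp6 -4.84 without water mouse 4). The bile acid transporter Slc10a2 differed by -0.76 ± 1.42, by 0.56 without water mouse 2 and by -2.05 without water mouse 4. The transporter subunit Slc51b, Osgin1, Abcc4 and the distal marker Car4 differed by -0.46 ± 0.31, -0.34 ± 0.26, 0.31 ± 0.26 and -0.41 ± 0.35, and without water mouse 2 Slc51b and Car4 differed by -0.22 and -0.011. Osgin1 was -0.091 without water mouse 3, Abcc4 0.11 without water mouse 4 and 0.46 without water mouse 3, and Car4 -0.64 without water mouse 3. The bile acid list, the distal ileum and colon list and the proximal list had mean differences of -0.43, -0.49 and 0.17 (medians over genes -0.16, -0.18 and 0.13) and did not pass (camera adjusted p = 0.426, 0.372 and 0.414). The bile acid difference was -0.076 without water mouse 2 and -0.78 without water mouse 4. Lactase (Lct), of the proximal intestine, was 12.39 in water mouse 2 and between 14.83 and 15.85 in the other 7 mice, and Creb3l3 differed by -0.16 ± 0.18 (-0.31 without water mouse 2 and -0.078 without voglibose mouse 4). Leaving out water mouse 2 turned the mean differences of both regional lists, to 0.09 for the distal and -0.32 for the proximal list. Leaving out voglibose mouse 2 also turned them, to 0.042 and -0.10. Without water mouse 4 both passed camera's preset test (adjusted p = 0.0130 and 0.0181), as they did with the smooth muscle list as a covariate (adjusted p = 0.0328 and 0.0184). With an estimated correlation, over all 8 mice, camera's adjusted p was 0.891 for the distal and 0.911 for the proximal list.

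Genes of the exocrine pancreas were high in voglibose mouse 2, in which 15 of 17 measured members exceeded all the other arrays. Pancreatic amylase (Amy2a5) stood at 14.09 there and at 5.32 or less elsewhere, and the carboxypeptidases Cpa1 and Cpb1 and chymotrypsinogen (Ctrb1), like it named after their values were seen, stood at 12.01, 12.26 and 11.17. Prss1, Cel, Try5 and Cela2a had differences of 0.83 ± 0.36, 0.74 ± 0.36, 1.72 ± 0.97 and 0.67 ± 0.39. Without this mouse they had 0.39, 0.32, 0.41 and 0.19. The list mean was 3.62 in this mouse and between -0.58 and -0.47 in the other 3 voglibose mice, so the mean difference of 1.03 (camera adjusted p = 0.000934, and adjusted p = 0.875 with an estimated correlation) became -0.01 without it. No member passed over all genes and 0 passed adjusted over the list alone.

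**Figure D3:**
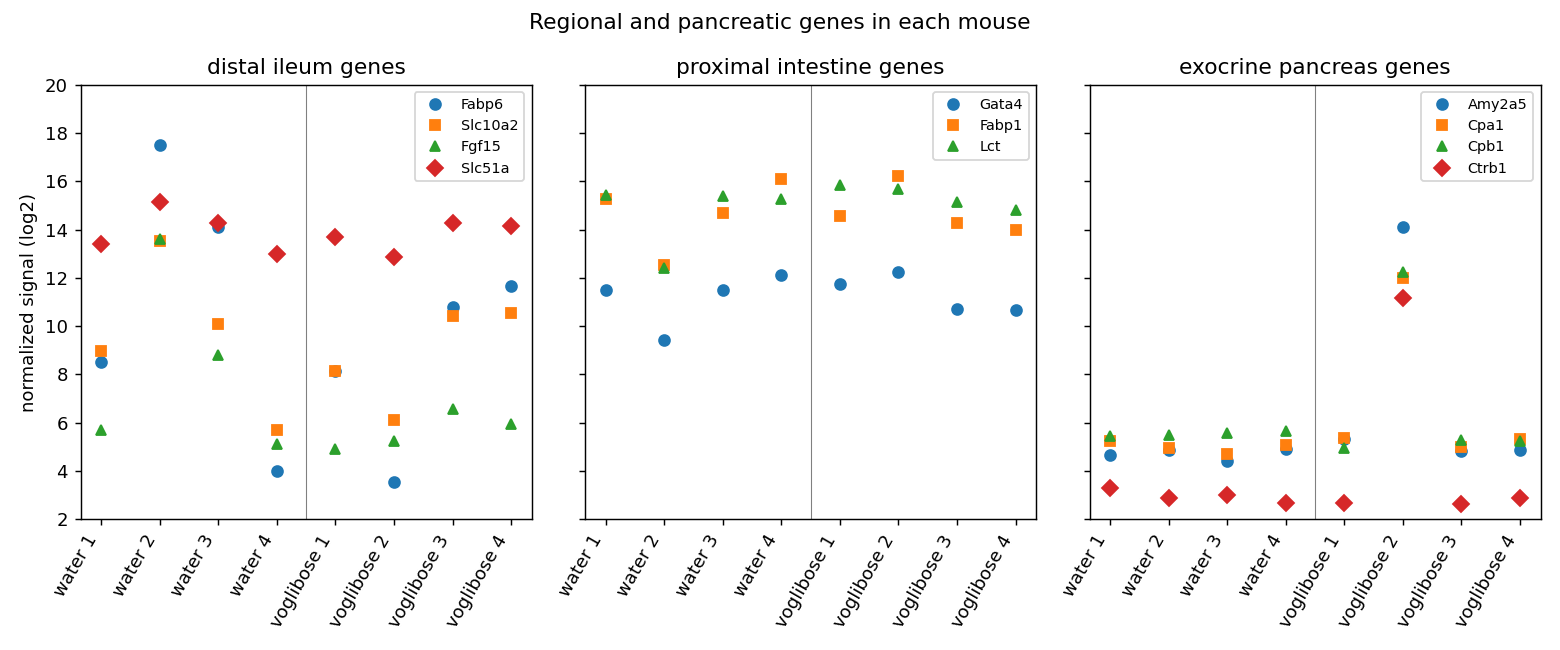
The panels show the log2 signal (y axis) of genes of the distal ileum, of the proximal intestine and of the exocrine pancreas in each of the 8 mice (x axis, 1 symbol per gene), picked from their lists after the values were seen. Fabp6 spans 3.54 to 17.50, Lct is lowest in water mouse 2 at 12.39, and the pancreatic genes are high in voglibose mouse 2, with Amy2a5 at 14.09.

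Other cell types also varied within the groups. The B cell and Peyer patch list was highest in water mouse 1 (1.13) and voglibose mouse 3 (0.95), where the other 6 mice lay between -0.61 and 0.11. Smooth muscle genes ranged from -1.22 in water mouse 4 to 1.31 in water mouse 2. Tuft cell markers were lower in 12 of 16 members (mean -0.23, median -0.14, and mean -0.11 without water mouse 2; camera adjusted p = 0.0683), with Gnat3 passing adjusted over this list alone (adjusted p = 0.0377). Across the 52 lists tested, 9 passed camera's preset test, 3 higher and 6 lower, 0 passed with an estimated correlation and 0 with fry (smallest adjusted p = 0.759), and 0 passed the exact permutation test after adjustment (smallest adjusted p = 0.880). The exact test could hardly pass, since its smallest p of 0.0286 fails adjustment over 52 lists unless many lists reach it. The 43 lists that did not pass had mean differences from -0.49 to 0.17 and adjusted p from 0.0557 to 0.966.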

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

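The tests of position along the intestine and of a response of the pancreatic genes to voglibose were chosen only after the results were seen, while the further list of acinar genes was written down before its values were. In each group of 4 mice, an array was singled out where its gap to the nearest other mouse took up most of the range of its group (Dixon's test). This held in 22 of 248 groups of values, where chance alone gives about 1 in 20, or 12.4, if the groups are independent. They are not, since list means hold many of the named genes and genes vary together. Many genes were also named for a small p. The excess over 12.4 is therefore not a test, and 1 unusual mouse can be counted many times. Water mouse 2 was the array apart in 8 of the 22 and voglibose mouse 2 in 4.

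Water mouse 2 stood low for Lct (12.39, others 15.28 to 15.43), Slc2a5 (12.78, others 13.93 to 14.11), Slc5a1 (16.60), Mgam (18.01), Creb3l3 (14.78), Cldn15 (15.60) and Ddit3 (9.50), and its list mean of xenobiotic metabolism was -0.32 where the other water mice had 0.23 to 0.30. Voglibose mouse 2 stood high for the exocrine pancreas list (3.62), Try5 (9.21) and Cck (8.92) and low for Tjp1 (11.08). In the other voglibose mice, mouse 1 was apart for Mgam (18.58) and for the list of nutrient receptors (0.081), mouse 3 for Il1b (7.90, others 6.78 to 6.89) and Slc5a4b (13.52), and mouse 4 for Kat7 (10.62), Mapk8ip3 (6.80) and Gnat3 (4.21). Among the remaining water mice, mouse 1 was apart for Saa3 (5.62), mouse 3 for Fbp1 (10.22) and mouse 4 for Muc2 (16.55).

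Of the 17 measured genes of the pancreas list, 15 were highest in voglibose mouse 2. The median excess of the list over the highest other array was 3.83. Clps and Zg16 were higher in another mouse (15.22 against 14.77, and 18.43 against 17.90). Clps is also in the Paneth cell list and Zg16 in the goblet cell list, so their signal need not come from pancreas. A response to voglibose is argued against by the other 3 voglibose mice, which lay a median of 0.12 (SE 0.087 over genes) from the water mean. Pancreatic tissue in the sample was tested with a further list of acinar genes, and this test missed: the median excess was 0.12 (SE 0.31) over 11 genes, which lies under the 0.5 set beforehand as speaking against it by more than the SE. That bound was judged wrong only after the value was seen, because a median hides that Sycn, Try10 and Cuzd1 exceeded every other array by 2.75, 1.92 and 1.18. Of the 11 genes, 7 lay below the median of every array in all 8 mice, where background keeps differences small. The median excess thus cannot decide for or against pancreatic tissue. Pancreatic tissue may therefore still account for the pattern, and a biological source other than treatment was not tested.

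Fabp6 and Slc10a2 spread widely within both groups and Fgf15 among water mice (SD 3.90, against 0.73 in voglibose mice), and pieces of ileum taken at different positions may account for it. The proximal list without its bile acid genes (12 genes) ran against the bile acid list over the 8 mice, with Pearson's r of -0.89 (exact permutation p = 0.00347, adjusted over 3 relations 0.00580) and Spearman's rho of -0.88 (exact permutation p = 0.00724, adjusted 0.0217), while r was -0.65 without the 2 mice farthest from the median. The distal list without these genes ran with it, at r of 0.73 (exact permutation p = 0.0408, adjusted 0.0408) and rho of 0.71 (exact permutation p = 0.0576, adjusted 0.0576), with r of 0.61 without the farthest 2. Lower activity of the bile acid receptor FXR as the whole account is argued against, since Slc10a2, which FXR represses, ran with Fgf15, which FXR induces, at r of 0.81 (exact permutation p = 0.00387, adjusted 0.00580), rho of 0.83 (exact permutation p = 0.0154, adjusted 0.0231) and r of 0.80 without the farthest 2. An effect of treatment on the bile acid genes stays open, with a list difference of -0.43 ± 0.50 (SE), of -0.076 without water mouse 2 and of -0.78 without water mouse 4.

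The position of the piece could also lie behind the list differences between the groups, so the distal list was added to the model as a covariate. The interferon difference went from -0.99 ± 0.63 to -1.20 ± 0.54 (SE) and that of oxidative phosphorylation from -0.27 ± 0.13 to -0.32 ± 0.10. Neither shrank, as position as the whole account would require. With the covariate both lay over 2 SE from 0, but without it the interferon difference lay within 2 SE. With 4 mice per group chance stays open for both (exact permutation p of the list means 0.171 and 0.0571). The covariate therefore does not decide their cause. The sugar transport difference went from 0.49 ± 0.38 to 0.33 ± 0.26, within 2 SE of 0, so position and treatment cannot be told apart for this list, because its spread over 4 mice per group is too wide. A difference in microbes or housing between cages was not tested, and neither was any other biological account.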

How the results depend on the processing

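The fits without water mouse 4 and voglibose mouse 2 and with the distal list as a covariate were chosen only after the results were seen. No probe set passed an adjusted p of 0.05 in any alternative run. The count of 1671 probe sets at an unadjusted p under 0.05 fell to 988 with only probe sets above the median signal (262 higher, 726 lower), since fewer were tested, and to 394 at 1.5-fold, and ran from 969 (without voglibose mouse 1) to 1906 with 1 mouse left out. It was 1144 and 2070 in the fits added later, and the share lower was 50.5% after a further quantile normalization. The 9 lists became 18 with the smooth muscle list as a covariate, a shift whose cause was not tested, and 0 with an estimated correlation and 0 with fry, which allow for correlated members. With 1 mouse left out they ran from 7 (without voglibose mouse 1) to 16 (without water mouse 4). The interferon, oxidative phosphorylation and proteasome lists passed in 19 of 19 refits and the sugar list in 18. All of these refits kept camera's preset correlation. That test called 12.6 of 52 lists on average in simulated lists of correlated members without a group effect. Passing every refit therefore does not show that a call would hold in other mice. With a replicate block 1529 probe sets and 7 lists passed their thresholds, the numbers did not pair the mice (correlations of deviations 0.02, -0.32, 0.01 and -0.18), and 0 arrays correlated best with their own number. Signal near background limits dim genes such as Tnf and Il6.

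For the values that turned direction, the cause was not tested. The enteroendocrine list mean was 0.0014 after quantile normalization and 0.032 without water mouse 4 and voglibose mouse 2, its camera adjusted p being 0.854 above the median signal, 0.577 without these mice and 0.952 with the distal covariate. The inflammatory list was 0.033 as a median, and the proximal list had an adjusted p of 0.535 with the distal covariate. Pcsk1 was 0.29 without these mice, and with the distal covariate Gip was -0.16, Slc10a2 0.21 and Il6 -0.011. With 1 mouse left out, list means ran from -0.0096 (without voglibose mouse 2) to 1.39 for the pancreas, -0.084 to 0.029 for enteroendocrine genes, -0.064 to 0.13 for junctions, -1.15 to 0.091 for the distal and -0.32 to 0.49 for the proximal list. Camera's adjusted p then ran from 0.622 to 0.975 for enteroendocrine genes, 0.403 to 0.987 for nutrient receptors, 0.0130 to 0.987 for the distal and 0.0181 to 0.841 for the proximal list. Log2 differences ran from -0.068 to 0.52 for Gcg, -0.27 to 0.13 for Pcsk1, -0.27 to 0.54 for Gip, -0.51 to 0.99 for Pyy, -0.077 to 0.40 for Slc2a2, -2.05 to 0.56 for Slc10a2, -0.13 to 0.14 for Tnf and -0.057 to 0.11 for Il6.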

Other observations

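The split of the mice for the count of adjusted calls was tested only after the result was seen, and the further gene lists below were written down after the report's values and before their own. Cholesterol biosynthesis genes were lower in 16 of 19 measured members with voglibose, by a mean of -0.21, and of -0.041 without water mouse 2 (camera adjusted p = 0.111). Insig1, which holds back the sterol-sensing transcription factors, and the sterol enzyme Msmo1 differed by -0.78 ± 0.29 and -0.76 ± 0.32 (SE), Msmo1 by -0.45 without water mouse 2, and Mvd and Fdps of the mevalonate pathway by -0.39 ± 0.18 and -0.48 ± 0.23, Fdps by -0.26 without voglibose mouse 2. Alpha-defensins of Paneth cells were higher in 18 of 22 members, by a mean of 0.14, and of 0.057 without water mouse 3 (camera adjusted p = 0.0557). Defa20 and Defa32 had the same mean and SD in both groups, so near-identical family members cannot be counted as separate measurements. No member of either list passed over all genes and 0 passed adjusted over the list alone.

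T cell and intraepithelial lymphocyte markers ranged from -0.96 in water mouse 2 to 0.56 in voglibose mouse 2. The antimicrobial and lectin list stood at 0.89 in water mouse 2 and between -0.33 and 0.10 in the other 7 mice. In this list Duoxa2, the maturation factor of an epithelial oxidase, had 9.41 ± 2.89 in water and 7.34 ± 1.36 in voglibose mice (SD, n = 4), and Reg4 differed by -0.73 ± 0.36 (SE).

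Chance can be excluded neither for the count of 1671 probe sets nor for that of 9 lists. The 8 mice can be split into 4 and 4 in 35 ways, and 5 of the 35 splits, the real one included, gave at least 1671 probe sets at an unadjusted p under 0.05 and 1.2-fold, with 2110 as the highest of the others. For the 9 lists past camera's preset test, 31 of the 35 splits gave as many, and the highest other gave 27. The splits decide nothing for the 0 adjusted calls of the real one, since 35 of 35 reach a count of 0 by definition; the highest other gave 1.

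One hypothesis was that the lower Ccr2, Cd14 and Ccl8 reflect fewer recruited monocytes in the ileum of voglibose mice. A further list of 21 measured monocyte genes had a mean difference of -0.12 ± 0.10 (SE), 7 higher and 14 lower, with -0.052 without voglibose mouse 4 and -0.19 without voglibose mouse 2, and did not pass (exact permutation p = 0.314, adjusted over 3 hypotheses 0.714). Ccl12 differed by -0.91 ± 0.29, while Ccl7 and Chil3 differed by 0.40 ± 0.18 and 0.41 ± 0.18, so a smaller monocyte influx was neither shown nor excluded.

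A second hypothesis was that the higher Slc2a5, Fbp1 and Tkfc follow the carbohydrate-sensing factor ChREBP, encoded by Mlxipl. Its other targets, 16 measured, had a mean difference of -0.025 ± 0.091, with 7 higher and 9 lower (exact permutation p = 0.714, adjusted 0.714). The difference was -0.099 without voglibose mouse 2 and 0.020 without water mouse 4. The value lies under the 0.1 set beforehand as speaking against ChREBP, by more than its SE. By the rule set beforehand, the result thus went against ChREBP. It does not lie under 0.1 by 2 SE, a margin considered only after the value was seen. Since members went both ways, ChREBP was not shown, and the list mean alone does not exclude it as the account of the 3 genes. Of the list, Pklr and Mlxipl differed by 0.54 ± 0.26 and 0.49 ± 0.24 (0.29 and 0.31 without water mouse 2), and Arrdc4 and Me1 by -0.46 ± 0.19 and -0.70 ± 0.34 (Me1 -0.42 without water mouse 2).

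A further hypothesis was that lower Gsdmc2, Gsdmc4 and tuft cell genes mark a weaker type 2 response of the epithelium. The 21 measured genes of a list for it had a mean difference of -0.32 ± 0.34 (exact permutation p = 0.514, adjusted 0.714), 10 higher and 11 lower, and of 0.0048 without water mouse 2. Gsdmc3 had 10.44 ± 3.24 in water and 7.81 ± 0.78 in voglibose mice (SD, n = 4) and Pla2g4c 7.80 ± 5.43 and 5.18 ± 0.45, so the spread among water mice was wider than the difference, and without water mouse 2 they differed by -1.21 and 0.087.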
